A study of Homo sapiens with 16 samples.

How the data were processed

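The series measured microRNAs (miRNAs) in human acral skin, the skin of the hands and feet. Per the labels, each of 16 samples was a fresh, untreated 3 mm full-thickness punch biopsy from the dorsum of the hand, the palm, the dorsum of the foot or the sole, with 4 biopsies per site. Total RNA including small RNA was dephosphorylated, ligated to pCp-Cy3 and hybridised to a one-colour Agilent human miRNA array, 1 array per biopsy, on 2 slides of 8 arrays. A number from 1 to 4 in the sample titles recurs in all 4 sites. Taking equal numbers as the same donor is an assumption, since the design text names distinct individuals of each site. Donor pairs and the donor block rest on it throughout. Each number gives a hand pair and a foot pair, so the 8 pairs over both limbs are not 8 independent units. After site means were removed, arrays with the same number had a mean correlation across miRNAs of 0.207, with a lowest of -0.619, and 19 of 24 pairs exceeded 0.1. Arrays of other numbers on the same slide had 0.0573 (24 pairs). The first slide held replicates 1 and 2 of every site and the second slide held replicates 3 and 4.

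Per the file headers, the array files held spot signals as fluorescence intensity from Agilent Feature Extraction 10.5.1.1, background-subtracted and spatially detrended within each array, with no normalization between arrays. The deposited series matrix held log2 intensity for the same 16 arrays. Its columns shared a single distribution, with medians from 6.03987 to 6.04059 and a common maximum of 15.8. The authors named Feature Extraction and Partek as their software, but not the steps, the offset or the base of the logarithm, which was taken as 2. All 851 human miRNA names of the arrays were found in the matrix, and each matrix column was checked to correlate best with its own array file. The matrix served as an alternative, and the comparisons used the array files.

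The background-subtracted signal was averaged over the spots of each probe that were not marked as outliers, then summed over the probes of a miRNA. Each array was divided by its 75th percentile over the 165 miRNAs detected on all 16 arrays, brought to a common scale, floored at 18.88 (4.24 on the log2 scale) and log2 transformed. A miRNA counted as detected on an array when at least 1 of its probes was well above background on 50% or more of its spots. The 271 miRNAs detected on at least 4 of 16 arrays were tested. One tested miRNA lay at the floor on every array. No saturated spot was found. Probes against viral miRNAs and hsa-miR-106a, which has no probe of that name, were not analysed here.

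Differences were tested with limma 3.58.1 in R 4.3.3, as a fit of 4 site means to all 16 arrays with no donor or slide term, followed by eBayes. There were 7 comparisons, namely volar (palm and sole) against non-volar skin, palm against dorsum of hand, sole against dorsum of foot, foot against hand, dorsum of foot against dorsum of hand, sole against palm, and the interaction, which is the sole difference minus the palm difference. Adjusted p values are Benjamini-Hochberg values of limma over the 271 miRNAs of a comparison, with a threshold of 0.05. Errors after a log2 fold change are standard errors (SE), and those after a mean are standard deviations (SD). Where every array of a site fell below detection, the fold against the floor is given as a lower bound.

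For each comparison the text names the 12 largest rises and the 12 largest falls past the threshold, and the 5 smallest p values where fewer than 5 miRNAs passed. It also names the miRNAs of the HOX gene clusters, miR-203, miR-205, miR-211 and miR-204, and examples from miRNA lists. These rules, 17 miRNA lists and most alternatives were fixed before the data were examined. The lists were HOX-cluster miRNAs, the epithelial miR-200 family, keratinocyte, melanocyte, dermal fibroblast and mesenchymal, smooth muscle, striated muscle, endothelial, erythrocyte, leukocyte, neuronal and glial, neuroendocrine and sensory, and adipocyte miRNAs, miR-17-92 and related clusters, the let-7 family, the 14q32 imprinted cluster, and miRNAs of inflamed and wounded skin. The 15 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01 and with an estimated correlation, and by fry, which tests a list by itself. Their p values were adjusted over the lists of a comparison. Striated muscle and neuronal and glial miRNAs had 2 tested members each and are described by their members.

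Positions of probe targets are on hg19, per the file headers, and names of containing genes come from the RefSeq annotation of a later assembly. Alternatives covered the scaling, the background step, the summary of probes, the floor, the filter, the series matrix, a donor block, a slide block, the model of the spread and leaving out each array. Others were added after the data were seen. Arrays give no read depth, so signal over background and 4 arrays per site limit the precision. Simulated data had 271 miRNAs, 20 runs, 40 changed miRNAs per run and independent normal noise. In them the volar comparison recovered 79.25% of changes of 1 log2 unit and 99.25% of changes of 2. Of its calls, 5.43% were false. The palm comparison recovered 60.5% of changes of 1 log2 unit, and the sole comparison 60.25%. The simulation had no floor, no scaling step, no donor or slide effect and no correlation between miRNAs. These shares may therefore not carry over to the real arrays. Figures were drawn with matplotlib 3.10.9.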

Results

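MicroRNA levels were measured in 16 biopsies of acral skin, 4 from each of 4 sites. Palm and sole are volar skin, which is hairless and thick, and the dorsum of the hand and the dorsum of the foot are non-volar skin. The number of detected miRNAs per array ranged from 185 in palm replicate 2 to 287 in dorsum of hand replicate 2. Its mean was 251 ± 25.5 in the dorsum of the hand, 227 ± 30.4 in the palm, 243 ± 30.9 in the dorsum of the foot and 248 ± 10.7 in the sole (SD, n = 4 each). The factor that scaled each array ranged from 0.404 in palm replicate 2 to 1.52 in dorsum of foot replicate 1. The most abundant miRNAs, as mean log2 signal over all arrays, were let-7a (15.32), miR-451 of red blood cells (15.25), let-7b (14.61), let-7f (14.60), miR-23a (14.46) and miR-1246 (14.18). The keratinocyte miRNA miR-205 had a mean of 12.68.

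A pair of features differed between arrays within sites. The probe set named miR-923, which binds a fragment of 28S ribosomal RNA, made up 57.2% of the signal in dorsum of hand replicate 4 and 56.3% in dorsum of foot replicate 2, against 4.18% to 30.7% in the other arrays. The mean log2 signal of the 5 erythrocyte miRNAs was 7.73 ± 0.58 in the dorsum of the hand, 9.14 ± 0.93 in the palm, 9.18 ± 1.20 in the dorsum of the foot and 7.38 ± 0.52 in the sole (SD, n = 4 each).

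**Figure D1:**
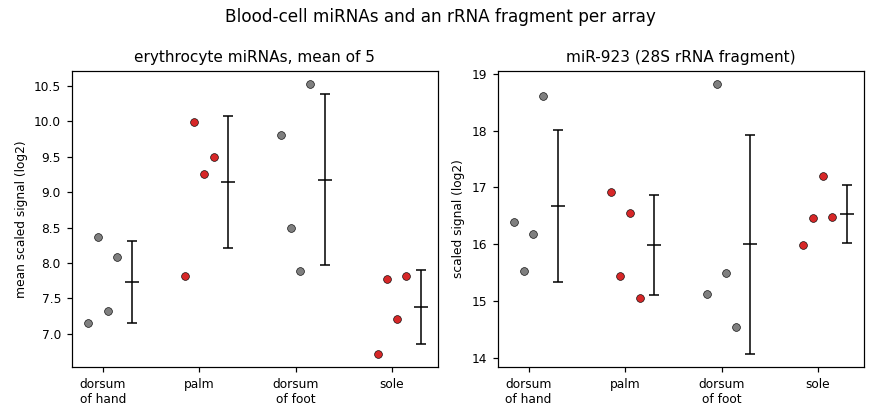
Mean log2 scaled signal of the 5 erythrocyte miRNAs (left) and log2 scaled signal of the 28S rRNA fragment miR-923 (right) for each of 16 arrays by skin site. Each point is an array, red for volar and grey for non-volar skin, with the mean and SD of 4 arrays beside it; the erythrocyte mean was 9.14 in palm and 9.18 in dorsum of foot, against 7.73 in dorsum of hand and 7.38 in sole.

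Volar skin was compared with non-volar skin over both limbs, the contrast that the series title names. In volar skin miR-211 was higher and miR-31 was lower, and these were the largest differences in each direction. The melanocyte miRNA miR-211, encoded inside the melanocyte gene TRPM1 (chromosome 15, 31357262 to 31357281, minus strand), had a mean log2 signal of 6.82 ± 0.75 in volar and 4.46 ± 0.26 in non-volar skin (SD, n = 8 each). It was detected on 8 of 8 volar and 4 of 8 non-volar arrays. The keratinocyte miRNA miR-31, encoded inside MIR31HG (chromosome 9, 21512126 to 21512141, minus strand), had 4.38 ± 0.28 in volar skin, close to the floor, and 7.19 ± 1.32 in non-volar skin (SD, n = 8 each). It was detected on 2 of 8 volar and 8 of 8 non-volar arrays. Let-7a, let-7c, let-7d and let-7f rose, while miR-143, a miRNA of smooth muscle and other contractile cells, and miR-193a-3p fell.

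With limma, 22 of 271 miRNAs passed the threshold, 12 higher and 10 lower in volar skin, and 56 had an unadjusted p under 0.05. The log2 fold change was 2.37 ± 0.23 for miR-211 (adjusted p = 2.45e-05) and -2.80 ± 0.31 for miR-31 (adjusted p = 5.21e-05), each in the same direction in 8 of 8 donor pairs. MiR-193a-3p fell by 1.79 ± 0.35 (adjusted p = 0.00518, 8 of 8 pairs). The next falls were miR-1246 (-1.44 ± 0.27, adjusted p = 0.00488, 7 of 8 pairs) and miR-143 (-0.99 ± 0.15, adjusted p = 0.00108, 8 of 8 pairs). Smaller falls were those of miR-17* (-0.82), miR-24-1* (-0.79), miR-22 (-0.64), miR-27a (-0.49), miR-140-5p (-0.42) and miR-27b (-0.39). Their adjusted p values ran from 0.0174 to 0.0438. Among the rises, miR-146a, which restrains innate immune signalling (chromosome 5, 159912383 to 159912400, plus strand), changed by 0.91 ± 0.16 (adjusted p = 0.00305, 8 of 8 pairs). MiR-455-3p, encoded inside the collagen gene COL27A1, rose by 0.68. MiR-221* rose by 0.82, miR-29b-1* by 0.77, miR-200b* by 0.61 and miR-342-5p by 0.60. The adjusted p values of these 5 ran from 0.00488 to 0.00799. MiR-513c (0.45, adjusted p = 0.0453) was below detection on all non-volar arrays and in all 4 palms, and was detected in all 4 soles. All 22 miRNAs had the same sign in the palm and sole comparisons and on both slides, which their choice on the mean of these largely builds in. In 14 of them the direction was shared by all 8 pairs. At each limb alone, 14 of the 22 passed in palm against dorsum of hand and 3 in sole against dorsum of foot. Of the 22, 1 passed at both limbs and 6 at neither. Slides 1 and 2 alone gave 2.09 and 2.65 for miR-211 and -2.46 and -3.15 for miR-31. There 3 and 9 miRNAs passed.

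By list, the 9 let-7 miRNAs, which act in differentiation, were all higher in volar skin, with a median log2 fold change of 0.45. Their camera adjusted p was 6.82e-05, and adjusted p = 0.281 with an estimated correlation. Let-7a (0.59), let-7c (0.39), let-7d (0.62) and let-7f (0.64) passed over all miRNAs, and 8 of 9 passed when adjusted over the list alone. Let-7d (adjusted p = 0.0505) and let-7f (adjusted p = 0.0596) did not pass with a donor block. The let-7 median was 0.33 on slide 1 and 0.55 on slide 2. The 3 smooth muscle miRNAs were lower, with a median of -0.74 (camera adjusted p = 0.00275; adjusted p = 0.278 with an estimated correlation). MiR-143 passed over all miRNAs. All 3, with miR-145 and miR-145*, passed when adjusted over the list alone. MiR-145* is the opposite strand of miR-145, so in every comparison the list may hold fewer independent changes than members. Their median was -0.56 on slide 1 and -0.91 on slide 2. Of 8 keratinocyte miRNAs, miR-31 and miR-27b fell, and 3 passed when adjusted over the list alone. The list median was -0.29, with -0.39 and -0.19 on the slides (camera adjusted p = 0.00348; adjusted p = 0.327 with an estimated correlation). Other keratinocyte miRNAs did not pass, among them miR-203 (0.29 ± 0.30, adjusted p = 0.643) and miR-205 (-0.45 ± 0.25, adjusted p = 0.333). The melanocyte list had a median of 0.75 (adjusted p = 0.0768). MiR-211 was its 1 member of 3 past the threshold, with miR-204 at -0.22 ± 0.29 (adjusted p = 0.738). MiR-204 and miR-211 are near-identical in sequence. Taken without the floor, the probes of miR-211 were at 2.70 and 2.57 and those of miR-204 at -0.36 and -0.33. How well probes tell these or the let-7 members apart was not tested.

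The 4 tested HOX-cluster miRNAs, which are encoded among the genes that set position along the body, had a median of 0.43 in volar skin. Their camera adjusted p was 0.0509, and 0.0109 with a donor block. Without that block, no list passed camera with an estimated correlation in any comparison (lowest adjusted p = 0.255). The log2 fold changes were 0.78 ± 0.25 for miR-196a (adjusted p = 0.0809), 0.39 ± 0.13 for miR-196b (adjusted p = 0.0887), 0.47 ± 0.20 for miR-10a (adjusted p = 0.20) and 0.29 ± 0.24 for miR-10b (adjusted p = 0.589). None passed over all miRNAs with limma, 3 had an unadjusted p under 0.05, and 3 passed when adjusted over the list alone. MiR-196a and miR-196b passed with a donor block (adjusted p = 0.00602 and 0.0335). The miR-200 family, which keeps epithelial cells from becoming mesenchymal, had a median of 0.29 (adjusted p = 0.139); miR-200b* rose and 3 of 6 passed when adjusted over the list alone. The remaining lists did not pass with camera in volar skin. By fry, HOX-cluster (adjusted p = 0.0285), melanocyte (adjusted p = 0.00365), endothelial (adjusted p = 0.0454) and adipocyte miRNAs (adjusted p = 0.0497) passed as well. The medians, with the adjusted p of camera, were -0.0049 for fibroblast (adjusted p = 0.667), 0.18 for endothelial (adjusted p = 0.380), -0.12 for erythrocyte (adjusted p = 0.667) and 0.14 for leukocyte miRNAs (adjusted p = 0.220). Further medians were 0.14 for adipocyte (adjusted p = 0.312), 0.19 for miR-17-92 (adjusted p = 0.742) and -0.09 for 14q32 miRNAs (adjusted p = 0.220). Neuroendocrine miRNAs had a median of 0.01 and a mean of -0.01 (adjusted p = 0.742), and inflamed skin miRNAs a median of 0.04 and a mean of -0.19 (adjusted p = 0.667). The striated muscle miRNAs miR-1 (-0.69, adjusted p = 0.444) and miR-133b (-0.83, adjusted p = 0.241) did not pass. Nor did the neural miRNAs miR-128 (0.19, adjusted p = 0.443) and miR-338-3p (-0.60, adjusted p = 0.229). MiR-338-3p passed with a donor block (adjusted p = 0.0439).

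With a donor block 26 miRNAs passed, 18 of them among the 22. The 4 lost were let-7d, let-7f, miR-27a (adjusted p = 0.0505) and miR-140-5p (adjusted p = 0.0556). The number past the threshold was 14 when arrays were scaled by all human miRNAs or by the median, 10 in the series matrix, 3 without scaling and 1 with normexp background correction. Scaling by all human miRNAs gave 42.9% of calls higher, against 54.5% as reported. With normexp miR-211 shrank to 0.58 (adjusted p = 0.707) and miR-31 to -1.07 (adjusted p = 0.173), and miR-200b* and miR-342-5p turned slightly negative. With the floor doubled miR-211 was at 1.59 and miR-31 at -1.95. The number was 11 without palm replicate 3, 13 without sole replicate 3 or sole replicate 4, and 14 without palm replicate 1, palm replicate 2 or sole replicate 1.

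**Figure D2:**
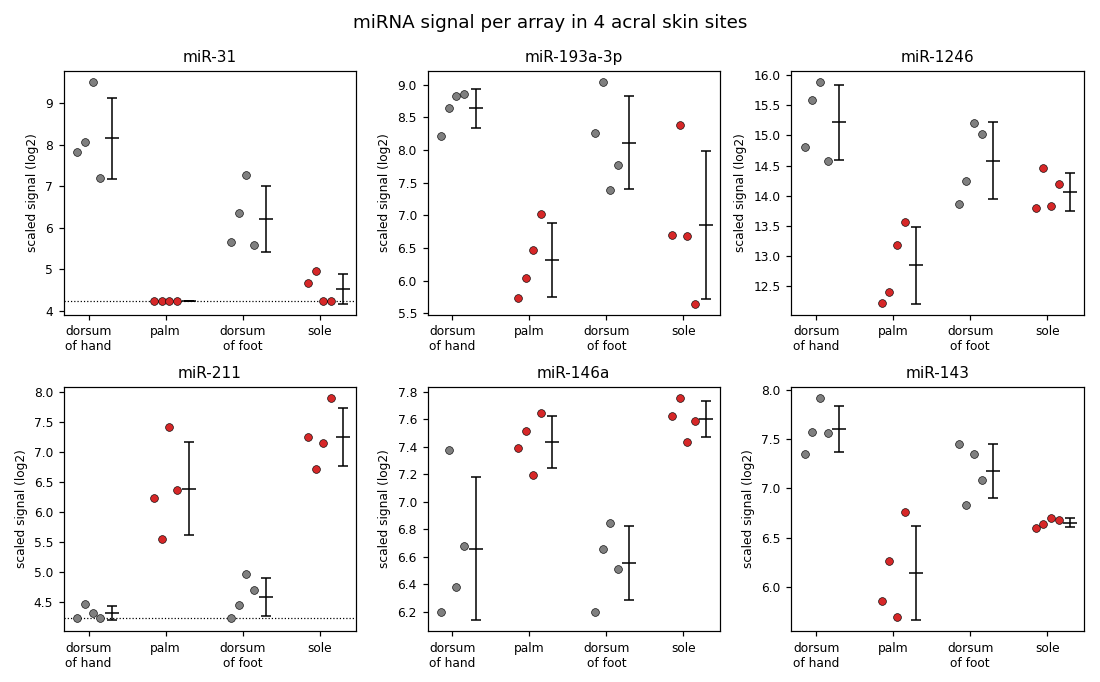
Log2 scaled signal of 6 miRNAs in each of 16 arrays by skin site, with red points for volar and grey points for non-volar skin and the mean and SD of 4 arrays beside them; the dotted line is the floor of 4.24. MiR-31 lay at the floor in all 4 palms, and the volar and non-volar means of miR-211 were 6.82 and 4.46.

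**Figure D3:**
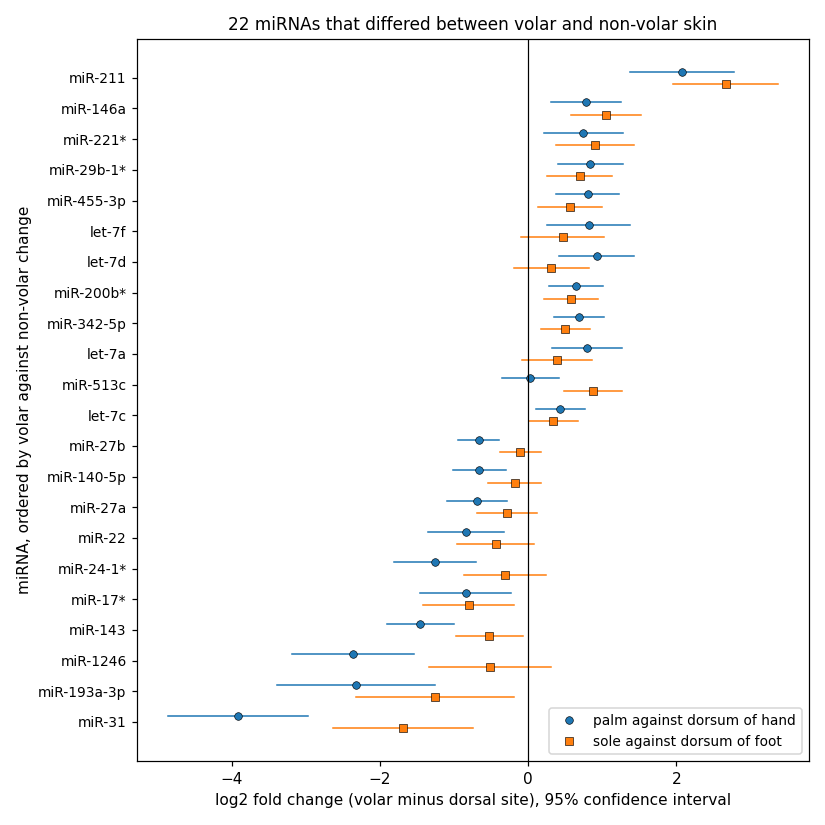
Log2 fold changes with 95% confidence intervals of limma for the 22 miRNAs that differed between volar and non-volar skin, shown for palm against dorsum of hand (blue circles) and sole against dorsum of foot (orange squares). All 22, chosen on the mean of these differences and so likely to share a sign, have the same sign at both limbs, from miR-211 (2.07 in palm and 2.66 in sole) to miR-31 (-3.92 in palm and -1.69 in sole).

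On the hand, palm was compared with the dorsum. MiR-31 was at the floor in all 4 palms and had a mean log2 signal of 8.16 ± 0.98 in the dorsum of the hand (SD, n = 4), at least 15.1-fold lower in palm. Its opposite strand miR-31* was likewise below detection in all 4 palms and at least 2.97-fold lower. MiR-1246 fell from 15.21 ± 0.62 to 12.85 ± 0.64 (SD, n = 4 each). MiR-193a-3p fell from 8.64 ± 0.30 to 6.32 ± 0.56, and miR-143 from 7.60 ± 0.23 to 6.14 ± 0.48 (SD, n = 4 each). MiR-211 rose from 4.32 ± 0.11 to 6.39 ± 0.77 and miR-652 from 5.03 ± 0.29 to 6.13 ± 0.34 (SD, n = 4 each).

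With limma, 16 miRNAs passed, 7 higher and 9 lower in palm, and 67 had an unadjusted p under 0.05. Of the 16, 14 had the same direction in all 4 donor pairs. The log2 fold changes were -3.92 ± 0.44 for miR-31 (adjusted p = 0.000120), -2.36 ± 0.38 for miR-1246 (adjusted p = 0.00184), -2.32 ± 0.50 for miR-193a-3p (adjusted p = 0.0129), -1.57 ± 0.41 for miR-31* (adjusted p = 0.0326) and -1.46 ± 0.21 for miR-143 (adjusted p = 0.00106). They were 2.07 ± 0.33 for miR-211 (adjusted p = 0.00184) and 1.102 ± 0.24 for miR-652 (adjusted p = 0.0129). The other falls were miR-24-1* (-1.25), miR-27a (-0.69), miR-27b (-0.67) and miR-140-5p (-0.66). The other rises were let-7d (0.92), miR-29b-1* (0.84), miR-455-3p (0.80), miR-342-5p (0.69) and miR-200b* (0.65). Adjusted p values of these 9 ran from 0.00822 to 0.0414. All 16, chosen on the mean of both slides, had the same sign on each, where miR-31 had -3.72 and -4.12 and miR-211 had 1.53 and 2.61. Within slides 1 and 2, 5 and 0 miRNAs passed with limma, and 35 and 67 had an unadjusted p under 0.05.

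Of the lists, let-7 (median 0.60, camera adjusted p = 0.000245), miR-17-92 (0.65, adjusted p = 0.00682) and erythrocyte miRNAs (1.82, adjusted p = 0.0359) were higher in palm. For let-7 adjusted p = 0.313 with an estimated correlation, and for the other lists 0.384. Smooth muscle (-1.02, adjusted p = 0.00194), keratinocyte (-0.47, adjusted p = 0.00194) and 14q32 miRNAs (-0.22, adjusted p = 0.0359) were lower. With an estimated correlation, adjusted p = 0.284, 0.313 and 0.384 in that order. The 14q32 median was 0.19 with normexp. The erythrocyte signal as a covariate left the miR-17-92 median at 0.07 (adjusted p = 0.748). Let-7d alone passed among 9 let-7 miRNAs over all miRNAs, and 7 passed when adjusted over the list alone. In the miR-17-92 list none passed over all miRNAs with limma, and 7 had an unadjusted p under 0.05. Adjusted over the list alone, miR-20b (1.37), miR-20a (1.04), miR-25 (0.89) and miR-17 (0.65) rose and miR-17* (-0.84) fell. Of these, miR-25 (adjusted p = 0.0268), miR-20b and miR-17* (adjusted p = 0.0499 each) passed over all miRNAs with a donor block. MiR-486-5p (2.03 ± 0.62), miR-144* (2.18 ± 0.75) and miR-451 (1.82 ± 0.66) were the 3 erythrocyte miRNAs that passed when adjusted over the list alone. Over all miRNAs their adjusted p ran from 0.0614 to 0.0944. Of 8 keratinocyte miRNAs, miR-31, miR-31* and miR-27b fell. MiR-203 was at 0.13 ± 0.43 (adjusted p = 0.901) and miR-205 at -0.68 ± 0.35 (adjusted p = 0.255). Among HOX-cluster miRNAs, miR-196a was at 1.17 ± 0.36 (adjusted p = 0.0614, and 0.00566 with a donor block). Others were miR-196b at 0.36 ± 0.19 (adjusted p = 0.249), miR-10a at 0.54 ± 0.28 (adjusted p = 0.252) and miR-10b at 0.17 ± 0.34 (adjusted p = 0.793). The list passed camera with a donor block (adjusted p = 0.0327) and not without it (adjusted p = 0.107). Without the block, it did not pass with an estimated correlation either. MiR-204 was at 0.03 ± 0.41 (adjusted p = 0.983). On slides 1 and 2 the medians were 0.44 and 0.94 for let-7, 0.48 and 0.83 for miR-17-92, 1.19 and 1.74 for erythrocyte, -0.57 and -1.51 for smooth muscle, -0.54 and -0.22 for keratinocyte and -0.19 and -0.20 for 14q32 miRNAs.

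A donor block raised the number to 31 with all 16 kept, among them miR-146a (0.78, adjusted p = 0.0279), miR-22 (-0.84, adjusted p = 0.0147) and miR-486-5p (2.03, adjusted p = 0.0147). The number was 6 with scaling by all human miRNAs or without scaling, 1 with normexp, under which miR-24-1* turned slightly positive, 7 with the erythrocyte signal as a covariate and 34 when only these arrays were fitted. Scaling by all human miRNAs gave 16.7% of calls higher, against 43.8% as reported. The number was 5 without palm replicate 2, 6 without dorsum of hand replicate 1, 8 without palm replicate 3, 9 without palm replicate 1, 26 without dorsum of hand replicate 2, and 39 and 38 without dorsum of foot replicates 2 and 4.

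On the foot, sole was compared with the dorsum. MiR-211 rose from 4.59 ± 0.31 in the dorsum of the foot to 7.26 ± 0.49 in the sole (SD, n = 4 each), and was detected on 3 of 4 arrays of the dorsum. MiR-146a rose from 6.55 ± 0.27 to 7.60 ± 0.13 (SD, n = 4 each). MiR-513c and miR-513b, encoded on chromosome X, were below detection in the dorsum of the foot and detected in all 4 soles, at least 1.83-fold and 1.97-fold higher.

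With limma, 4 miRNAs passed, all higher in the sole and in all 4 donor pairs, and 37 had an unadjusted p under 0.05. The log2 fold changes were 2.66 ± 0.33 for miR-211 (adjusted p = 0.000371), 1.04 ± 0.22 for miR-146a (adjusted p = 0.0292), 0.98 ± 0.22 for miR-513b (adjusted p = 0.0462) and 0.87 ± 0.18 for miR-513c (adjusted p = 0.0292). MiR-31 was at -1.69 ± 0.44 (4 of 4 pairs, adjusted p = 0.0989) and did not pass. Slides 1 and 2 gave 2.64 and 2.69 for miR-211 and -1.20 and -2.19 for miR-31. No miRNA passed on either slide alone with limma, and 14 and 32 had an unadjusted p under 0.05. MiR-211 was the 1 miRNA past the threshold at both limbs, against 0.236 expected if the calls were independent, and 15 of the 16 palm calls had the same sign in the sole. Across all tested miRNAs, which are not independent replicates, the palm and sole differences had a correlation of 0.0502 (Spearman 0.122).

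Of the lists, the miR-200 family (median 0.47, camera adjusted p = 0.0195), melanocyte (1.11, adjusted p = 0.0453) and let-7 miRNAs (0.31, adjusted p = 0.0218) were higher in the sole. For each, adjusted p = 0.374 with an estimated correlation. Erythrocyte (-2.06, adjusted p = 0.000409) and miR-17-92 miRNAs (-0.49, adjusted p = 0.000958) were lower, with adjusted p = 0.374 for each with an estimated correlation. With the erythrocyte signal as a covariate the miR-17-92 median turned to 0.25, and with normexp the melanocyte median was -0.23. Adjusted over the list alone, 2 of 6 miR-200 miRNAs passed, miR-200a (0.71) and miR-200b* (0.58). So did 3 of 5 erythrocyte miRNAs, miR-486-5p (-2.27), miR-451 (-2.06) and miR-144 (-2.69). None of these 5 passed over all miRNAs. No let-7 or miR-17-92 miRNA passed by either adjustment with limma. MiR-211 was the 1 melanocyte miRNA that passed, and miR-204 was at -0.48 ± 0.41 (adjusted p = 0.689). Leukocyte miRNAs had a median of 0.11 and a mean of -0.07, and inflamed skin miRNAs 0.06 and -0.02; neither list passed with camera. On slides 1 and 2 the medians were 0.31 and 0.54 for miR-200, 0.43 and 1.79 for melanocyte, 0.31 and 0.29 for let-7, -2.05 and -1.80 for erythrocyte and -0.46 and -0.38 for miR-17-92 miRNAs. Among HOX-cluster miRNAs, miR-196a was at 0.38 ± 0.36 (adjusted p = 0.710), miR-196b at 0.42 ± 0.19 (adjusted p = 0.340), miR-10a at 0.39 ± 0.28 (adjusted p = 0.679) and miR-10b at 0.40 ± 0.34 (adjusted p = 0.689). MiR-203 was at 0.46 ± 0.43 (adjusted p = 0.710) and miR-205 at -0.23 ± 0.35 (adjusted p = 0.949).

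With a donor block 4 passed, with miR-486-5p (-2.27, adjusted p = 0.0215) in place of miR-513b (adjusted p = 0.0574), and the melanocyte list no longer passed (adjusted p = 0.242). The number was 7 with scaling by the median, 1 with the erythrocyte signal as a covariate and 0 with limma after normexp. It was 0 as well among miRNAs detected on all arrays, a filter that leaves out miR-211, miR-513b and miR-513c untested. MiR-513b (-0.29) and miR-513c (-0.30) turned negative with normexp. The number was 8 without dorsum of hand replicate 4, 2 without dorsum of hand replicate 1 or 2 or dorsum of foot replicate 2, and 1 without palm replicate 3 or 4, dorsum of foot replicate 1 or 4, or any of the 4 soles.

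Foot was compared with hand over volar and non-volar skin. MiR-196b, encoded in the HOXA cluster beside HOXA10 (chromosome 7, 27209116 to 27209134, minus strand), was lower on the foot, with a mean log2 signal of 5.39 ± 0.35 against 6.11 ± 0.28 (SD, n = 8 each). The means were 5.18 ± 0.35 against 5.93 ± 0.23 in the dorsum and 5.60 ± 0.22 against 6.29 ± 0.22 in volar skin (SD, n = 4 each). With limma it was the 1 miRNA to pass (-0.72 ± 0.13, adjusted p = 0.0246, 8 of 8 pairs), and 21 had an unadjusted p under 0.05. It was -0.64 on slide 1 and -0.80 on slide 2. The next smallest p values were those of miR-378 (0.64 ± 0.17, adjusted p = 0.299), miR-513c (0.42, adjusted p = 0.469), miR-429 (0.42, adjusted p = 0.535) and miR-532-5p (0.31, adjusted p = 0.535), none of which passed. Other HOX-cluster miRNAs were at -0.61 ± 0.25 for miR-196a (adjusted p = 0.603), -0.21 ± 0.20 for miR-10a (adjusted p = 0.961) and 0.15 ± 0.24 for miR-10b (adjusted p = 0.961). MiR-211 was at 0.57 ± 0.23 (adjusted p = 0.602), miR-203 at 0.23 ± 0.30 (adjusted p = 0.961), miR-205 at -0.14 ± 0.25 (adjusted p = 0.961) and miR-204 at 0.05 ± 0.29 (adjusted p = 0.983).

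As a list, HOX-cluster miRNAs were lower on the foot with a median of -0.41 (camera adjusted p = 0.0245; adjusted p = 0.355 with an estimated correlation). MiR-196b was the 1 of 4 that passed when adjusted over the list alone. The 14q32 miRNAs were lower as well (-0.13, adjusted p = 0.0245; adjusted p = 0.441 with an estimated correlation). The miR-200 family (0.21, adjusted p = 0.0283), fibroblast (0.16, adjusted p = 0.0271) and miR-17-92 miRNAs (0.17, adjusted p = 0.0283) were higher. With an estimated correlation, adjusted p = 0.423, 0.423 and 0.594 in that order, and no member of these lists passed by either adjustment with limma. By slide the medians were -0.60 and -0.12 for HOX-cluster, 0.28 and 0.10 for miR-200 and 0.26 and 0.12 for miR-17-92 miRNAs. The fibroblast median was 0.39 and -0.06, and that of 14q32 miRNAs was 0 and -0.22. With a donor block the same 1 miRNA passed and the miR-200 family did not (adjusted p = 0.0599). No miRNA passed with limma under any other scaling tried, in the series matrix, with normexp, with the floor at 50% of its value, without a filter or with a trend. None passed when any of dorsum of hand replicates 2 and 3, palm replicates 2, 3 and 4, dorsum of foot replicates 1 and 2 or sole replicates 1, 2 and 4 was left out, and 2 passed without dorsum of hand replicate 4 or dorsum of foot replicate 4.

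The dorsum of the foot was compared with the dorsum of the hand, and the sole with the palm. In the dorsum of the foot miR-31 was at 6.22 ± 0.79 against 8.16 ± 0.98 in the dorsum of the hand (SD, n = 4 each), and it was detected on all 8 arrays. That difference of -1.94 ± 0.44 (adjusted p = 0.166) had the smallest p, and no miRNA passed with limma, while 31 had an unadjusted p under 0.05. The next were miR-196b (-0.75 ± 0.19, adjusted p = 0.185), miR-652 (0.88 ± 0.24, adjusted p = 0.206), miR-31* (-1.41 ± 0.41, adjusted p = 0.270) and miR-363 (1.81 ± 0.55, adjusted p = 0.270). MiR-196a was at -0.22 ± 0.36 (adjusted p = 0.970), miR-10a at -0.14 ± 0.28 (adjusted p = 0.988) and miR-10b at 0.04 ± 0.34 (adjusted p = 1). Further values were miR-211 at 0.27 ± 0.33 (adjusted p = 0.859), miR-203 at 0.06 ± 0.43 (adjusted p = 1), miR-205 at -0.36 ± 0.35 (adjusted p = 0.80) and miR-204 at 0.31 ± 0.41 (adjusted p = 0.883).

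Between the dorsal sites 8 lists passed with camera. Higher on the foot were miR-17-92 (median 0.71, 13 of 13 members positive, adjusted p = 1.07e-07), erythrocyte (1.67, adjusted p = 0.00129), adipocyte (0.21, adjusted p = 0.0270) and neuroendocrine miRNAs (0.47, adjusted p = 0.0466). For neuroendocrine miRNAs adjusted p = 0.406 with an estimated correlation, and for the other 3 lists 0.255. Lower were 14q32 (-0.35, adjusted p = 0.00129), inflamed skin (-0.14, adjusted p = 0.0270), keratinocyte (-0.15, adjusted p = 0.0420) and smooth muscle miRNAs (-0.42, adjusted p = 0.0420). For keratinocyte miRNAs adjusted p = 0.406 with an estimated correlation, and for the other 3 lists 0.255. Adjusted over the list alone, miR-486-5p (2.00) and miR-451 (1.86) of the erythrocyte list, miR-31 and miR-31* of the keratinocyte and inflamed skin lists, and miR-196b of the HOX-cluster list passed. By slide the medians were 0.64 and 0.82 for miR-17-92, 1.06 and 1.30 for erythrocyte, 0.26 and 0.04 for adipocyte and 0.29 and 0.78 for neuroendocrine miRNAs. They were -0.12 and -0.37 for 14q32, -0.39 and -0.11 for inflamed skin, -0.37 and -0.12 for keratinocyte and -0.32 and -0.52 for smooth muscle miRNAs. With a donor block miR-31 and miR-196b passed (adjusted p = 0.0466 each), and keratinocyte (adjusted p = 0.0562) and smooth muscle miRNAs (adjusted p = 0.0731) did not. Without dorsum of foot replicate 2, 9 miRNAs passed, and 2 passed without dorsum of hand replicate 4 or dorsum of foot replicate 3. With normexp the medians of 14q32 (0.42), inflamed skin (0.22) and smooth muscle miRNAs (0.09) were above 0. The erythrocyte signal as a covariate left the miR-17-92 median at 0.12 (adjusted p = 0.156).

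Between sole and palm no miRNA passed with limma, and 29 had an unadjusted p under 0.05. The smallest p values were those of miR-513c (0.84 ± 0.18, adjusted p = 0.0989), miR-513b (0.93 ± 0.22), miR-429 (0.77 ± 0.20), miR-196b (-0.69 ± 0.19) and miR-486-5p (-2.30 ± 0.62), the last 4 with an adjusted p of 0.129. MiR-211 was at 0.86 ± 0.33 (adjusted p = 0.361), miR-196a at -1.001 ± 0.36 (adjusted p = 0.360) and miR-10a at -0.29 ± 0.28 (adjusted p = 0.806). Others were miR-10b at 0.27 ± 0.34 (adjusted p = 0.861), miR-203 at 0.40 ± 0.43 (adjusted p = 0.845), miR-205 at 0.09 ± 0.35 (adjusted p = 0.960) and miR-204 at -0.21 ± 0.41 (adjusted p = 0.868). Erythrocyte miRNAs were lower in the sole (median -2.02, camera adjusted p = 0.000193; adjusted p = 0.439 with an estimated correlation). Of 5 members, 3 passed when adjusted over the list alone. HOX-cluster miRNAs were lower (-0.49, adjusted p = 0.0394; adjusted p = 0.506 with an estimated correlation). MiR-17-92 (-0.33, adjusted p = 0.0259) and let-7 miRNAs (-0.22, adjusted p = 0.0488) were lower as scaled. For each, adjusted p = 0.554 with an estimated correlation. Without scaling their medians were 0.0055 and 0.12, and the let-7 median was 0.05 in the series matrix. The erythrocyte signal as a covariate turned the miR-17-92 median to 0.30. Fibroblast (0.38, adjusted p = 0.00418) and miR-200 miRNAs (0.38, adjusted p = 0.0278) were higher, with adjusted p = 0.439 and 0.506 with an estimated correlation. By slide the medians were -2.01 and -2.16 for erythrocyte, -0.59 and -0.39 for HOX-cluster, -0.12 and -0.49 for miR-17-92, -0.32 and -0.12 for let-7, 0.58 and 0.10 for fibroblast and 0.61 and 0.07 for miR-200 miRNAs. With a donor block miR-513c (0.84), miR-196a (-1.001), miR-196b (-0.69) and miR-486-5p (-2.30) passed (adjusted p = 0.0345 each). MiR-200 (adjusted p = 0.0516) and let-7 miRNAs (adjusted p = 0.0756) did not. With scaling by the median, 6 miRNAs passed.

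The interaction asked whether the volar difference was unlike on foot and hand. The erythrocyte miRNA miR-451 was higher in palm than in the dorsum of the hand (16.20 ± 0.75 against 14.38 ± 0.81) and lower in sole than in the dorsum of the foot (14.18 ± 0.77 against 16.24 ± 1.47; SD, n = 4 each). MiR-486-5p did likewise, with 9.81 ± 0.72 against 7.78 ± 1.07 on the hand and 7.51 ± 0.87 against 9.78 ± 1.06 on the foot (SD, n = 4 each). The erythrocyte list had a median interaction of -3.80 (camera adjusted p = 8.35e-06; adjusted p = 0.288 with an estimated correlation). It was -3.20 on slide 1 and -3.46 on slide 2, and 4 of 5 members passed when adjusted over the list alone. MiR-17-92 miRNAs had a median of -1.01 (camera adjusted p = 6.31e-07; adjusted p = 0.327 with an estimated correlation), which turned to 0.26 with the erythrocyte signal as a covariate. Of 13, 2, miR-25 (-1.40) and miR-20b (-2.06), passed when adjusted over the list alone.

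With limma no single miRNA passed, 33 had an unadjusted p under 0.05 and 12 had an adjusted p under 0.10. The largest in evidence were miR-486-5p (-4.31 ± 0.88, adjusted p = 0.0685), miR-652 (-1.51 ± 0.33, adjusted p = 0.0685), miR-451 (-3.89 ± 0.94, adjusted p = 0.0797), miR-363 (-3.18 ± 0.78, adjusted p = 0.0797) and miR-185 (-2.30 ± 0.62, adjusted p = 0.0919). MiR-31 was at 2.23 ± 0.62 (adjusted p = 0.0919) and miR-211 at 0.59 ± 0.46 (adjusted p = 0.653). The size for miR-31 depends on the floor, at which it lay in all 4 palms and 2 of 4 soles. HOX-cluster miRNAs were at -0.79 ± 0.51 for miR-196a (adjusted p = 0.591), 0.05 ± 0.26 for miR-196b (adjusted p = 0.928), 0.23 ± 0.48 for miR-10b (adjusted p = 0.837) and -0.15 ± 0.40 for miR-10a (adjusted p = 0.869). Further values were miR-203 at 0.34 ± 0.61 (adjusted p = 0.814), miR-205 at 0.44 ± 0.50 (adjusted p = 0.732) and miR-204 at -0.52 ± 0.58 (adjusted p = 0.732). Smaller interactions were those of keratinocyte (median 0.39, camera adjusted p = 0.0339), smooth muscle (0.63, adjusted p = 0.0426), 14q32 (0.39, adjusted p = 0.0426) and let-7 miRNAs (-0.33, adjusted p = 0.0426). With an estimated correlation, adjusted p = 0.438 for each of these 4. The let-7 median was 0.04 under scaling by the median and 0.14 without scaling. With normexp the 14q32 median turned to -0.67 and the direction of the let-7 test turned, at a median of -0.25. By slide the medians were 0.65 and 0.27 for keratinocyte, 0.42 and 0.98 for smooth muscle, 0.31 and 0.37 for 14q32, -0.03 and -0.56 for let-7 and -0.76 and -1.19 for miR-17-92 miRNAs. With a donor block miR-486-5p passed (adjusted p = 0.00473), and smooth muscle (adjusted p = 0.0692) and let-7 miRNAs (adjusted p = 0.0680) did not. In the interaction 14 miRNAs passed without dorsum of foot replicate 2, 6 without dorsum of foot replicate 3 and 2 without dorsum of hand replicate 4 or palm replicate 1. Without both arrays of the highest miR-923 signal 15 passed, among them miR-451 (-4.29) and miR-31 (2.58).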

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

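The patterns weighed in this part came from the results above. A prediction for each test of a cause was written before that test was run. The permutation tests of the erythrocyte signal and the look at the make-up of a regrouping were not among those predictions. Fits with a covariate, or with arrays left out on the ground of their signal, were added after the data were examined. Of 172 groups of 4 arrays checked for a single array far from the rest, 11 held one, against a nominal 8.6 at 1 in 20. That expectation does not apply at the floor. There any array above the rest counts as far, and a group wholly at the floor cannot be flagged. The numbers therefore cannot be weighed against each other. Let-7f was low in dorsum of foot replicate 2 (13.57, against 14.59 to 14.63 in the rest of its site) and in sole replicate 2 (14.53, against 14.89 to 14.92). MiR-451 was high in dorsum of hand replicate 2 (15.58, against 13.89 to 14.13), and miR-185 was high in sole replicate 4 (7.53, against 6.70 to 6.77). In 7 groups an array lay above the floor of 4.24 while the rest lay at it or within 0.02 of it, namely miR-513c in palm replicate 1 (4.35), miR-17* in palm replicate 4 (4.66) and sole replicate 2 (5.30), miR-31* in dorsum of foot replicate 3 (4.90), and miR-513b in dorsum of hand replicate 4 (4.98), palm replicate 1 (4.72) and dorsum of foot replicate 2 (4.56).

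An unlike volar difference on foot and hand was found for 6 lists, by the test of the interaction itself with the preset correlation. Their medians were -3.80 for erythrocyte, -1.01 for miR-17-92, -0.33 for let-7, 0.39 for keratinocyte (0.391), 0.63 for smooth muscle and 0.39 for 14q32 miRNAs (0.390), none of which passed with an estimated correlation.

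The first pattern weighed is the erythrocyte signal, high in palm and dorsum of foot and low in dorsum of hand and sole. Between sole and dorsum of foot, and between sole and palm, its mean differed by -1.80 and -1.76, each with an exact two-sided permutation p of 0.0286, the smallest that 4 against 4 arrays can give (adjusted p = 0.0571 each over 4 comparisons). By the same exact permutation test, palm against dorsum of hand (1.41, p = 0.0857) and dorsum of foot against dorsum of hand (1.45, p = 0.114) had an adjusted p of 0.114 each, and none of the 4 passed the threshold of 0.05. Scaling between arrays is argued against, since the highest median interaction of the list over the 4 other scalings was -3.17. Unequal blood content of the biopsies may account for the interaction of other miRNAs, since with the erythrocyte signal as a covariate the number of other miRNAs with an unadjusted interaction p under 0.05 went from 29 to 7, where chance gives 13.3. In those 29, chosen on the interaction itself, its median absolute value went from 1.33 to 0.409 and its median SE from 0.394 to 0.474. Over all miRNAs the covariate raised the median SE 1.48-fold, so a loss of precision may account for part of the drop in number. Whether blood content differed by how the biopsies were taken or by the vessels of each site, a biological difference that the design names, stays open and untested.

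The next pattern is the low miR-31 of volar skin, -2.80 ± 0.31. The log2 fold change was -2.81 ± 0.32 with the miR-923 signal as a covariate (adjusted p = 0.000139 with limma). It was -2.88 ± 0.28 with the erythrocyte signal (adjusted p = 3.76e-05 with limma). Mean miR-923 signals were 15.99 in palm and 16.53 in sole, against 16.68 and 16.00 in the dorsum of hand and of foot. Both signals were near balance over skin types, so neither covariate could move the volar contrast much. That balance argues against unequal RNA degradation or blood content as the whole cause, as far as these signals track them. How well they do was not tested. Another RNA bound by the miR-31 probes stays open, since the sequence of one probe lies within the other. Their highest value was -4.45, taken without the floor that the -2.80 carries. The probes of miR-31*, which have another sequence, were at -1.27 and -3.88, likewise without the floor. Their signals were too low to settle the question. A difference between volar and non-volar skin, in the cells present or in their miR-31, is a hypothesis that may account for it, found and tested on the same data.

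The last pattern is the higher let-7 family of volar skin, with a median of 0.45. The median was 0.44 with the miR-923 signal as a covariate and 0.46 with the erythrocyte signal. As above, both signals were near balance over skin types, so neither covariate could move the median much. That balance argues against unequal RNA degradation or blood content as the whole cause, as far as these signals track them. Signal shared between near-identical members stays open, as no table separates it, so the family may hold fewer independent changes than members. A biological difference between the skin types stays open as well.

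In splits of the same arrays that ignored donor pairs and slides, chance is argued against for the volar count. Only the real split of 100 gave 22 miRNAs, and the highest other gave 3. The real split also gave most for palm against dorsum of hand (1 of 35, 16 against at most 0) and sole against dorsum of foot (1 of 35, 4 against at most 2). There 1 of 35 is the smallest share possible, and over 7 comparisons it does not exclude chance. For foot against hand, with a real count of 1, 4 of 100 splits gave 1 or more and the highest other gave 6. That share was under the limit of 0.05 set beforehand, but for 1 of 7 comparisons it does not exclude chance. Where the real count was 0 every split gave as many, so the splits say nothing about chance. This was so for dorsum of foot against dorsum of hand (35 of 35, highest other 43), sole against palm (35 of 35, highest other 1) and the interaction (100 of 100, highest other 16). The regrouping with 43 points to a structure of the samples. Its sides held 3 and 1 arrays from the dorsum of the hand and differed in mean miR-923 signal (17.50 against 15.18) and erythrocyte signal (7.76 against 9.14). Splits along the slides gave 0 in palm and dorsum of hand, 1 in sole and dorsum of foot, 2 in the dorsal sites and 0 in sole and palm; with the 2 dorsal sites the real split gave 0, and 2 with a donor block. Splits that part all donor pairs as the real one does were too few for a share under 0.05. There were 8 for each pair of sites, which is all that exist, and 4 to 6 among the 100 drawn for the others, the real one included. The highest other count among them was 0, except in the dorsal sites (43). With donor pairs kept, chance is thus not excluded for any comparison. For volar skin, foot against hand and the interaction this is a limit of the draw. Further splits that part all pairs exist there and were not run.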

How the results depend on the processing

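Fits with the miR-923 or erythrocyte signal as a covariate, with donor as a random block, with robust eBayes, with a floor filter, and without the arrays of highest miR-923 signal or of lowest signal were chosen after the data were seen. Over all settings, 43 named miRNA results past the threshold were checked 1629 times. Of the checks, 1105 kept direction and call, 519 lost the call and 5 turned direction. Only miR-1246 in palm kept both in all 39 settings; in volar skin miR-31, miR-211, miR-143, miR-193a-3p, miR-1246 and miR-146a lost the call in 1 or 2. The 39 list results were checked 1321 times: 969 kept, 345 lost and 7 turned, by the direction of the camera test. The sign of a median could change without that, as given below. Causes were not tested except where a setting's construction gives one.

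Scaling by the 75th percentile of all human miRNAs gave 14 miRNAs for volar against non-volar skin, 6 for palm against dorsum of hand, 2 for sole against dorsum of foot, 0 for foot against hand, 1 for the interaction and 24 lists. Quantile normalization gave 0 for foot against hand, 1 for the interaction and 25 lists. Scaling by the median gave 14 for volar, 7 for sole against dorsum of foot, 0 for foot against hand and 6 for sole against palm. No scaling gave 3 for volar, 6 for palm, 0 for foot against hand and 1 for dorsum of foot against dorsum of hand. Scaling moved the median of all miRNAs by over 0.1 in the interaction (0.37 by the median, 0.42 unscaled, against 0.09). It also did so in sole against dorsum of foot (0.21 by the median), in the dorsal sites (-0.15 by the median, -0.13 unscaled), in sole against palm (0.17 and 0.22) and in palm (-0.20 unscaled). The share of calls that were higher was 42.9%, 33.3% and 40% in volar skin by all human miRNAs, unscaled and in the series matrix (54.5% as reported), 16.7%, 0% and 33.3% in palm, where the median gave 10.53% (43.8% as reported), and 80% in sole by quantiles (100% as reported).

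Normexp gave 1 for volar, 1 for palm, 0 for sole against dorsum of foot, 0 for foot against hand and 6 for the interaction. Its offset of 50, added to each spot, exceeds the floor of 18.88 used otherwise, so it shrinks log2 differences of dim miRNAs on every array. It also weighs more on dim arrays once they are scaled. How much of the lost calls this accounts for was not tested. It turned miR-200b* (-0.0017) and miR-342-5p (-0.0027) in volar skin, miR-24-1* in palm (0.015), miR-513b (-0.29) and miR-513c (-0.30) in sole, the 14q32 list in the dorsal sites (0.42) and in the interaction (-0.67), and the direction of the let-7 test in the interaction (median -0.25). With normexp the median alone changed sign for 14q32 in palm (0.19) and foot against hand (0.07), melanocyte (-0.23) and miR-200 (-0.03) in sole against dorsum of foot, inflamed skin (0.22) and smooth muscle (0.09) in the dorsal sites, and smooth muscle in the interaction (-0.10). Total gene signal gave 2 and the brightest probe 1 in sole against dorsum of foot, as did the doubled floor (1). With the floor at 50% of its value the count was 8 in palm, 0 for foot against hand and 1 for the interaction. The series matrix gave 10 for volar, 2 for sole against dorsum of foot and 0 for foot against hand. With only miRNAs detected on all arrays, fewer are tested: 6 in volar, 27 in palm, 0 in sole against dorsum of foot and 5 in the interaction. This filter leaves out miR-31, miR-211, miR-513b and miR-513c, so it says nothing about them. No filter gave 12 for volar, 5 for palm, 1 for sole against dorsum of foot and 0 for foot against hand, and limma warned that most of its residual variances were 0, which makes eBayes unreliable there. A donor (replicate) block gave 31 in palm, 2 in the dorsal sites, 4 in sole against palm and 1 in the interaction, and changed no other call of a named result than those given in the results. A slide block gave 26 in palm, fitting only the groups compared gave 34 there, and a trend gave 0 for foot against hand. An estimated correlation left 0 of the 39 list calls of camera. Over the same 105 tests, fry made 14 calls, some of them on other lists.

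Without both arrays of highest miR-923 signal the counts were 1 in sole against dorsum of foot, 0 for foot against hand, 1 in the dorsal sites and 15 in the interaction, and without the array of lowest signal 14 in volar, 5 in palm and 0 for foot against hand. Donor as a random block gave 30 in palm and 1 in the interaction, robust eBayes 1 and the floor filter 4 in the interaction. The erythrocyte covariate gave 7 in palm, 1 in sole against dorsum of foot and 24 lists. It turned miR-17-92 in sole against dorsum of foot (0.25), sole against palm (0.30) and the interaction (0.26), and the direction of the neuroendocrine test in the dorsal sites (median 0.028), where the keratinocyte median alone changed sign (0.02). Scaling did so for let-7 in sole against palm and in the interaction, as the results give. The miR-923 covariate gave 42 in volar and 28 in palm.

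With each array left out in turn, counts ranged from 11 (without palm replicate 3) to 27 in volar, 5 (palm replicate 2) to 39 (dorsum of foot replicate 2) in palm, 1 to 8 (dorsum of hand replicate 4) in sole against dorsum of foot, 0 to 2 for foot against hand, 0 to 9 and 0 to 14 (both dorsum of foot replicate 2) in the dorsal sites and the interaction, 0 to 0 in sole against palm, and 25 (dorsum of hand replicate 2) to 39 lists. Signal over background limits miR-31, miR-31*, miR-211, miR-513b and miR-513c, whose low sites lie near the floor of 4.24.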
